A study of Mus musculus with 10 samples.

How the data were processed

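RNA from bone marrow derived macrophages of C57BL/6 mice was measured by stranded mRNA sequencing (TruSeq kit, per the labels' protocols). The 10 libraries form 5 groups of 2: untreated cells labelled wild type (WT), untreated cells labelled Tlr4 knockout (KO), cells of both labels collected after 6 h in medium with 5% fetal bovine serum and 2% bovine serum albumin (the control medium), and KO cells pre-treated in medium with Poly(I:C), a synthetic double-stranded RNA. The labels do not say how long the Poly(I:C) pre-treatment lasted or whether its medium held the same serum and albumin. For untreated cells they give no medium or time, so each response to a medium below is a difference from untreated cells. Wild-type cells given Poly(I:C) were not analysed here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the samples of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

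The submitters' processing notes name Trim Galore 0.2.8, STAR 2.4.0d, RSEM 1.2.12 and DESeq2, with no roles or settings. The authors' genome build is not given in the sources used here. The authors deposited one table of whole numbers per gene and library and one table of rlog values on a log2 scale, both with Ensembl gene identifiers. Of 45318 identifiers, 44585 matched a symbol in the GENCODE M21 annotation of GRCm38, and unmatched identifiers held at most 0.125% of any library's total. Coordinates printed here are those of that annotation and may not be of the authors' build.

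The deposited whole numbers turned out not to be raw read counts, and they are treated as a signal. In each library the low values lie on a grid, as happens when reads are multiplied by one factor and rounded. Some whole numbers are skipped where the factor is above 1, and some are doubled where it is below 1. A search over factors in steps of 0.0005 found one factor per library, from 0.687 to 1.9025, and dividing by it gave 18.3 to 56.5 M recovered reads. Multiplying back and rounding gave the deposited value for 99.6% or more of the values from 1 to 200. In the 4 libraries with a factor below 1 this holds for any such factor, by arithmetic. There it does not check the factor, which rests on the search alone. In 6 libraries the factor was above 1, so that the units outnumber the reads. The deposited totals were 25.2 to 26 M in untreated cells, 42 and 41.1 M in WT control, 25.7 and 26.7 M in KO control, and 47.5 and 51.7 M in KO Poly(I:C). The source of the factors is not given in the sources used here. The median-of-ratios offsets of the signal table and the library offsets of the rlog table differed by at most 0.0106 log2. Rounding removes information on the lowest genes, and the signal cannot be read as counting error.

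Before the data were examined, the groups, the comparisons, 32 gene lists, the rule for named genes and the other settings to be tried were fixed. A count model (edgeR's quasi-likelihood test) had been planned on the assumption of raw counts and was not used for any value printed here, because the unit turned out to be another. The replacement test, its filter and its pseudocount were chosen after the data were examined, and a count fit had been looked at first. The replacement was limma 3.58.1 in R 4.3.3. Each value was divided by the library's total times its own trimmed mean of M values (TMM) factor, with 30% of M and 5% of A values trimmed, and expressed as CPM. Genes with a value of at least 10 in at least 2 libraries were kept, which left 13171 of the 20687 genes above 0. The test was limma with a trend on log2(CPM + 0.1), with 1 coefficient for each of the 5 groups fitted to all 10 libraries (5 residual degrees of freedom and 4.81 prior ones). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Fold changes are on the log2(CPM + 0.1) scale, which understates the change of low genes. Levels are means ± SD over the 2 libraries of a group. No fold is given against a group in which a gene is listed at 0.

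There were 7 comparisons, including the interaction of genotype and control medium. For the 26 lists with at least 5 tested genes, limma's camera compared list members with all other genes at a preset correlation of 0.01, with adjustment over the lists of a comparison. The lists cover lipid handling, immune activation, energy metabolism, growth, stress, macrophage markers and markers of other cell types that a marrow culture could hold. With a correlation estimated from the data, 0 of the 78 camera calls among 182 tests held, so every camera value below rests on the preset. The overlap of calls between comparisons that share no library was set against the product of the numbers of calls divided by the genes tested. All comparisons use the same spread per gene, so genes of small spread are more easily called in each. An overlap above this product can therefore arise without a shared response.

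The rule for named genes took Tlr4 first. For each comparison it then took called genes with a mean of at least 10 CPM in the higher group, ranges that did not overlap and a symbol that is not a predicted, clone or pseudogene name. Of these it kept the 6 that rose most and the 6 that fell most. For the interaction, which had no condition on ranges, and for Poly(I:C) against untreated cells it kept 3 each way. From each list it took up to 3 members that rose and 3 that fell with the smallest adjusted p. In untreated cells, Lrmda, Akap2, Ptprd, the pseudogene copies of Rpl35a, Gm10243 and Mid1-ps1 fall outside the rule. So do S100a9 and Mmp8 in WT control cells. All of these were chosen after their values were seen. Results for 2 genes that the rule names are not reported here.

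Settings listed then were median-of-ratios scaling, no filter on low values, limma on the rlog table, the replicate number as a block, only the groups compared, each library left out in turn, and, for the lists, an estimated correlation and limma's fry. The Wald test of DESeq2 was listed as well and was not run, since it also assumes raw counts. Settings added after the data were seen were the deposited values with no further scaling, scaling by totals alone, pseudocounts of 0.02 and 0.5 CPM, limma voom on the recovered reads, and leaving out both libraries whose factor exceeded 1.4. The test was also run on simulated data made from the real means and spreads, with 200 genes changed by known folds. For genes changed 2-fold, the share recovered was 82.1% for KO untreated against WT untreated (12933 genes), 74.6% for KO control against KO untreated (12936 genes) and 64.2% for the interaction (12925 genes). For genes changed 1.5-fold the interaction recovered 11.9%, and KO untreated against WT untreated 59.7%. The changed genes were drawn from well-covered ones only. The real comparisons called far fewer or far more genes than the simulated ones, so these shares do not give the power of the real tests.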

Results

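The transcriptome of mouse bone marrow derived macrophages, primary macrophages grown from marrow cells, was compared between cells labelled WT and cells labelled Tlr4 knockout in 5 groups of 2 libraries. TLR4 is the receptor for bacterial lipopolysaccharide, and the series asks how its loss bears on inflammatory signalling and on the lipid metabolism of macrophages. The groups were untreated cells of both labels, cells of both labels after 6 h in the control medium with serum and albumin, and KO cells pre-treated with Poly(I:C). Deposited totals ranged from 25.2 to 51.7 M units per library, behind which lay 18.3 to 56.5 M recovered reads. Lyz2, which encodes lysozyme, was the most abundant gene in all 4 untreated libraries, at 1.86% to 2.27% of the total. Replicates correlated at 0.992 to 0.994 on the log scale across genes, and no 2 libraries of a group were alike within sampling noise (chi-square per degree of freedom of 7.56 to 24.5). The first principal component held 83.5% of the variance. WT control and KO Poly(I:C) libraries lay on its positive side, at 71.7 to 106, and the libraries of the other 3 groups on its negative side, at −69.2 to −47.3. The Y-linked genes Ddx3y and Eif2s3y were present in every library, at 64.8 to 90.0 and 58.3 to 89.5 CPM, while Xist, which is expressed from the inactive X chromosome, reached at most 0.0561 CPM. Nnt, which carries a deletion in one C57BL/6 substrain, was present at 26.6 to 46.8 CPM in all libraries. One value per gene does not show whether the deleted part was read, so this level does not settle the substrain.

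Tlr4 itself (ENSMUSG00000039005, chromosome 4, 66827584 to 66930284, GRCm38) was present in every group. In untreated cells it stood at 64.5 ± 6.13 CPM (SD, n = 2) under the WT label and 44.6 ± 0.427 CPM under the KO label, a log2 difference of −0.53 (SE 0.14) that did not pass the test (limma, adjusted p = 0.35) except with the replicate block (adjusted p = 0.0375). After the control medium the levels were 35.4 ± 4.53 CPM in WT and 32.7 ± 2.70 CPM in KO cells (log2 −0.11, SE 0.14, limma adjusted p = 0.52). With scaling by totals alone this difference turned to 0.37 with an adjusted p of 0.0228. Poly(I:C)-treated KO cells had 56.3 ± 11.9 CPM, higher than KO control cells by 0.77 log2 (SE 0.14, limma adjusted p = 0.000836), but by 0.04 with scaling by totals alone (adjusted p = 0.787). The table gives one value per gene and does not show which part of the transcript the reads cover. Because the level of the targeted gene was not lost, genotypes are given below as labelled, and every direction between genotypes rests on the labels.

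**Figure D1:**
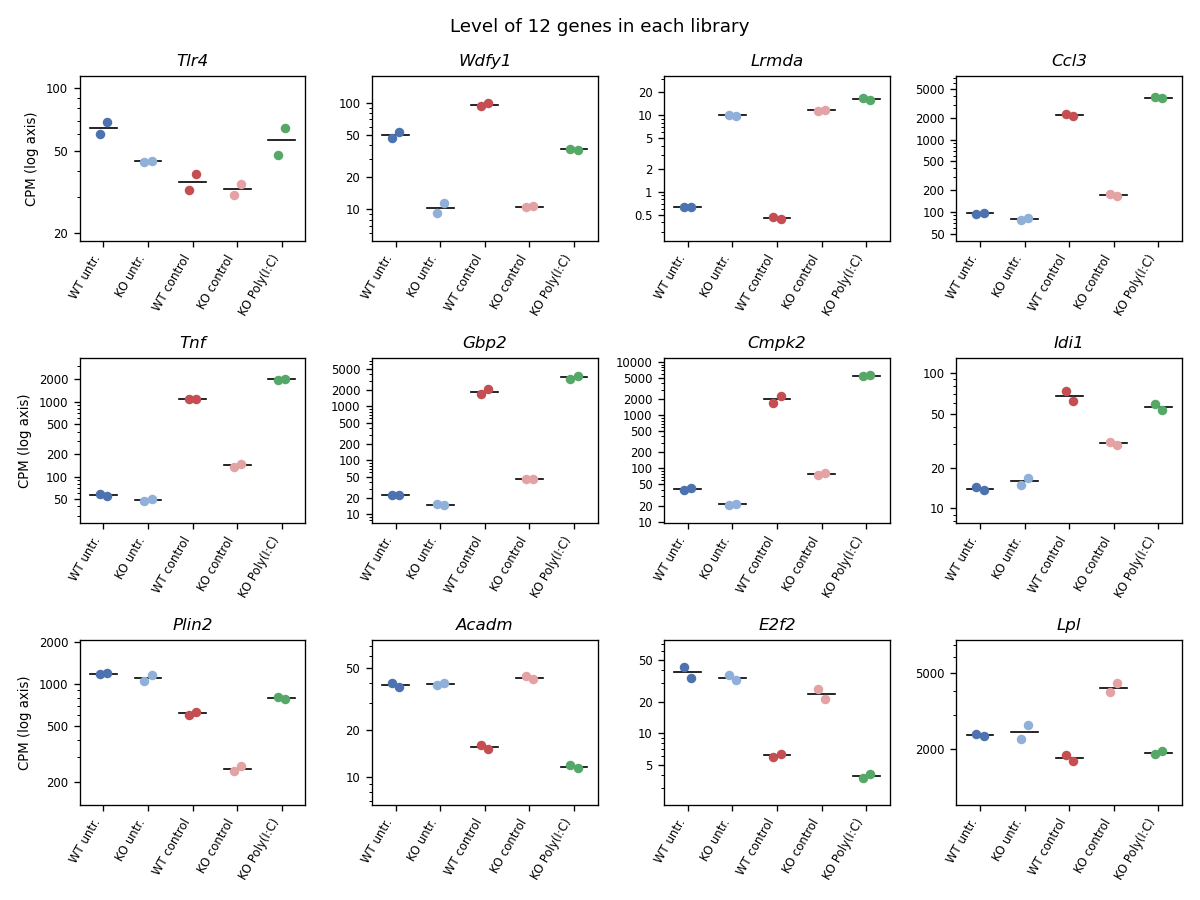
Normalised level (CPM, log axis) of 12 genes in each of the 10 libraries; each point is 1 library, each black line the mean of the 2 libraries of a group. Tlr4 lies between 32.7 and 64.5 CPM in all group means. Wdfy1 is at 10.3 and 10.6 CPM in untreated and control KO cells, but at 36.6 CPM in KO Poly(I:C) cells. Ccl3, Tnf, Gbp2 and Cmpk2 are highest in WT control and KO Poly(I:C) cells.

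In untreated macrophages few single genes passed the test between the genotypes. The inflammatory, interferon and lipid lists held almost none that passed over all genes. Of 49 interferon-stimulated genes, however, 34 were lower and 0 higher in KO cells when adjusted over the list alone (median log2 difference −0.548). Among the genes that passed, Wdfy1, an adaptor in TLR3 and TLR4 signalling, fell from 50.1 ± 4.35 CPM in WT to 10.3 ± 1.65 CPM in KO cells (log2 −2.28, SE 0.11, limma adjusted p = 1.74e-05). Lrmda, a gene linked to melanocyte differentiation, was at 0.627 ± 0.000477 CPM in WT and 9.96 ± 0.146 CPM in KO cells (log2 3.79, SE 0.14, limma adjusted p = 1.57e-06). Cmpk2, an interferon-inducible nucleotide kinase, was at 41.2 ± 2.03 CPM in WT and 21.1 ± 1.13 CPM in KO cells (log2 −0.96), a call that was lost in 8 settings.

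This comparison asks what the loss of TLR4 changes in cells with no pre-treatment. Of 13171 genes, 22 passed, 11 up and 11 down in KO cells, and 1144 had an unadjusted p under 0.05. Also lower in KO cells were Rab4a, a GTPase of recycling endosomes (log2 −0.99, from 12.6 to 6.31 CPM), Phf11b (−0.67) and Pdpn, which encodes podoplanin (−0.61). Higher were Zkscan3, a zinc finger repressor of autophagy genes (0.79, from 40.6 to 70.3 CPM), and Gng10, a G protein gamma subunit (0.76, from 22.5 to 38.1 CPM). These calls were lost in 7 settings for Rab4a and Phf11b, 5 for Pdpn and Gng10 and 4 for Zkscan3. Akap2, an anchoring protein of protein kinase A, and Ptprd, a receptor phosphatase, were higher by 3.19 and 3.74, from 0.628 ± 0.045 and 0.0957 ± 0.0421 CPM in WT cells. Akap2, Gng10 and Ptprd lie on chromosome 4 at 9.07, 7.84 and 10.2 Mb from Tlr4. The 22 include 4 copies of the ribosomal pseudogene Rpl35a with identical values, listed at 0 in untreated KO cells and at 0.576 ± 0.161 CPM in WT cells. They also include Gm10243, at 4.41 ± 0.183 CPM in KO and 0.873 ± 0.258 CPM in WT cells. In every control and Poly(I:C) library Gm10243 had the same value as the copy Rpl35a-ps3. These calls may therefore be one set of shared reads assigned differently, and the reads themselves were not examined. Mid1-ps1 on chromosome Y was listed at 0 in both WT libraries and at 2.25 ± 0.518 CPM in KO cells.

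Among 49 tested interferon-stimulated genes, 0 rose, 1 (Cmpk2) fell and 48 did not pass, while 34 were lower when adjusted over the list alone. Their median log2 difference was −0.548 (camera adjusted p = 3.19e-32, adjusted p = 0.357 with an estimated correlation). Among 39 inflammatory genes, 0 passed over all genes, and 1 was higher and 5 lower when adjusted over the list alone (median −0.0716, camera adjusted p = 0.000503, adjusted p = 0.357 with an estimated correlation). Of 24 cholesterol synthesis genes and 23 fatty acid oxidation genes, 0 passed over all genes and 0 when adjusted over the list alone, with camera adjusted p = 0.819 and 0.75. Camera placed 6 other lists lower in KO cells although 0 of their genes passed over all genes. Of 29 endoplasmic reticulum and integrated stress genes, 1 was lower when adjusted over the list alone (camera adjusted p = 1.06e-06, adjusted p = 0.357 with an estimated correlation). Of 34 immediate early genes, 5 were lower in this way (camera adjusted p = 3.18e-05, adjusted p = 0.357 with an estimated correlation). Of 28 glycolysis and hypoxia-inducible genes 1 was (camera adjusted p = 0.000208, adjusted p = 0.357 with an estimated correlation). Of 26 inflammasome and cell death genes, 2 were (camera adjusted p = 0.0183, adjusted p = 0.357 with an estimated correlation). Of 36 TCA cycle and respiratory chain genes, 0 were (camera adjusted p = 0.00148, adjusted p = 0.38 with an estimated correlation). Among 39 cell cycle genes 0 were (camera adjusted p = 0.00581, adjusted p = 0.929 with an estimated correlation). The count of 22 was sensitive to single libraries: it was 12 (9 up and 3 down) without WT untreated 1, 55 (41 and 14) without WT untreated 2, 16 (9 and 7) without KO untreated 1 and 14 (7 and 7) without KO untreated 2. It was 103 (29 and 74) with the replicate block. It was 2, both up, with only these groups in the fit. There Wdfy1, Akap2 and Ptprd lost their calls (limma adjusted p = 0.0676, 0.0676 and 0.0737), while their log2 differences were −2.28, 3.22 and 3.86.

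After 6 h in the control medium, WT-labelled macrophages had higher levels of all tested inflammatory and interferon-stimulated list members than untreated WT cells. Ccl5, a chemokine that attracts T cells and monocytes, went from 1.91 ± 0.841 to 1364 ± 222 CPM (log2 9.46, SE 0.23, limma adjusted p = 9.14e-10). Nos2, the inducible nitric oxide synthase, went from 3.45 ± 0.395 to 950.0 ± 172 CPM (log2 8.06), and Tnf from 55.9 ± 2.43 to 1096 ± 1.54 CPM (log2 4.29). Acod1, which makes itaconate from a TCA cycle intermediate, reached 7894 ± 349 CPM (log2 5.30). Most tested proliferation and fatty acid oxidation genes fell, and most sterol synthesis genes rose.

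The comparison measures the difference of WT cells after the control medium from untreated WT cells, for which the labels give no medium or time. Of 13171 genes, 4326 rose and 4354 fell. Relative to this split, scaling by totals alone gave 2267 up and 7690 down, with the median of all genes at −0.524, and the deposited scaling 5157 up and 3423 down, with the median at 0.145. The other genes that rose most were Il12b, the p40 subunit of IL-12 and IL-23 (log2 10.76, to 285 ± 73.2 CPM), Cxcl9 (8.61), the interferon-inducible Ifi205 (8.29) and Edn1, which encodes endothelin 1 (7.57). Those that fell most were Angptl4, a secreted inhibitor of lipoprotein lipase (−6.16, from 19.9 to 0.189 CPM), the sialyltransferase St6gal1 (−5.14), Eps8 (−4.24), the palmitoyltransferase Zdhhc14 (−4.15), Kctd12b (−4.10) and Rnf150 (−4.05).

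All 39 tested inflammatory genes rose (39 when adjusted over the list alone, camera adjusted p = 4.15e-21, adjusted p = 0.104 with an estimated correlation), among them the chemokines Ccl3 (log2 4.51) and Ccl4 (4.95). All 49 interferon-stimulated genes rose (49 when adjusted over the list alone, camera adjusted p = 9.33e-22, adjusted p = 0.33 with an estimated correlation), among them the GTPases Gbp2 (6.33) and Gbp5 (6.87). In the Toll-like receptor pathway, 28 of 39 rose, 6 fell and 5 did not pass (28 and 6 adjusted over the list alone, camera adjusted p = 0.000243, adjusted p = 0.401 with an estimated correlation). Tlr3, the receptor for double-stranded RNA, rose by 3.08, the adaptor Myd88 by 2.14 and the lipopolysaccharide co-receptor Cd14 by 2.68, while Tlr4 fell by 0.87 (SE 0.14, limma adjusted p = 0.000419). Antigen presentation genes split into 16 up, 2 down and 2 not passing of 20 (16 and 2 adjusted over the list alone, camera adjusted p = 0.000705, adjusted p = 0.513 with an estimated correlation), with the co-stimulatory receptor Cd40 up by 5.21. In the inflammasome and cell death list, 16 of 26 rose, 6 fell and 4 did not pass (16 and 6 adjusted over the list alone, camera adjusted p = 0.00689, adjusted p = 0.33 with an estimated correlation), with the inflammasome sensor Nlrp3 up by 3.82. Of 34 immediate early genes 26 rose, 1 fell and 7 did not pass (26 and 1 adjusted over the list alone, camera adjusted p = 2.27e-07, adjusted p = 0.185 with an estimated correlation).

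Metabolic lists moved as well. Of 24 cholesterol synthesis genes, 16 rose, 2 fell and 6 did not pass (16 and 2 adjusted over the list alone, camera adjusted p = 0.000148, adjusted p = 0.403 with an estimated correlation). Of 23 fatty acid oxidation genes, 1 rose, 18 fell and 4 did not pass (1 and 18 adjusted over the list alone, camera adjusted p = 3.13e-05, adjusted p = 0.122 with an estimated correlation), with the medium-chain dehydrogenase Acadm at −1.31 and the thioesterase Acot2 at −3.91. Of 28 glycolysis and hypoxia-inducible genes, 23 rose, 4 fell and 1 did not pass (23 and 4 adjusted over the list alone, camera adjusted p = 2.87e-05, adjusted p = 0.122 with an estimated correlation). The glucose transporter Slc2a1 rose by 2.68 and Pfkfb3, which drives phosphofructokinase, by 2.46. In the eicosanoid list 5 of 15 rose and 9 fell (5 and 9 adjusted over the list alone). Its median was −0.582 and its mean 0.151, because the prostaglandin enzymes Ptgs2 (7.52) and Ptges (4.26) rose steeply, and camera found no difference from other genes (adjusted p = 0.449). In the lipid uptake and storage list 12 of 23 rose and 6 fell (13 and 7 adjusted over the list alone, camera adjusted p = 0.219), a direction that flipped to 9 up and 11 down with scaling by totals alone. Of 39 cell cycle genes, 0 rose, 35 fell and 4 did not pass (35 adjusted over the list alone, camera adjusted p = 1.66e-08, adjusted p = 0.513 with an estimated correlation), such as E2f2 (−2.60), the replication helicase subunit Mcm4 (−1.67) and the mitotic kinase Aurkb (−2.69).

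The remaining lists of this comparison are given as counts of genes that rose and fell, with the same counts adjusted over the list alone. Of 22 oxidative stress genes under NRF2, 14 rose and 4 fell (14 and 4, camera adjusted p = 0.00938, adjusted p = 0.167 with an estimated correlation). Of 18 fatty acid synthesis genes 6 rose and 10 fell (6 and 10, camera adjusted p = 0.609), which flipped to 6 and 4 with the deposited scaling. Of 15 targets of the oxysterol receptor LXR 3 rose and 4 fell (3 and 4, camera adjusted p = 0.609), which flipped to 4 and 3 with the deposited scaling. Of 28 phospholipid and sphingolipid genes 16 rose and 6 fell (16 and 6, camera adjusted p = 0.0659), which flipped to 9 and 13 with scaling by totals alone. Of 36 TCA cycle and respiratory chain genes 10 rose and 6 fell (6 and 4, camera adjusted p = 0.609), against 2 and 31 with scaling by totals alone. Of 13 pentose phosphate and NADPH genes 4 rose and 7 fell (4 and 7, camera adjusted p = 0.575). Of 29 stress genes 6 rose and 10 fell (6 and 10, camera adjusted p = 0.615), against 11 and 10 with the deposited scaling. Of 31 lysosome and autophagy genes 10 rose and 9 fell (10 and 9, median −0.11, mean 0.0468, camera adjusted p = 0.973), against 5 and 23 with scaling by totals alone. Of 22 alternative activation genes 12 rose and 6 fell (12 and 6, camera adjusted p = 0.379). Of 23 macrophage identity genes 11 rose and 6 fell (11 and 6, camera adjusted p = 0.609), against 4 and 14 with scaling by totals alone. Of 10 osteoclast and M-CSF genes 3 rose and 4 fell (3 and 4, median −0.111, mean 0.15, camera adjusted p = 0.866).

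Markers of other cell types moved with the same groups. Of 14 tested neutrophil genes, 9 rose and 5 did not pass in WT control cells (9 adjusted over the list alone, camera adjusted p = 0.00938, adjusted p = 0.513 with an estimated correlation), 1 of the 14 (Lcn2) is also on the inflammatory list, and 9 stood at 1 CPM or more in untreated WT macrophages. Lcn2, an iron-sequestering protein, rose by 3.44, the G-CSF receptor Csf3r by 1.69, and the alarmins S100a8 and S100a9 by 2.60 and 1.71 to only 44.0 ± 3.37 and 37.3 ± 11.3 CPM. The neutrophil collagenase gene Mmp8 was at 194 ± 8.78 and 180 ± 6.55 CPM and did not pass (log2 −0.11). It passed at −0.63 with scaling by totals alone (adjusted p = 4.69e-05). Of 15 stromal genes, 7 rose, 0 fell and 8 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0501), and their median of 0.418 turned to −0.0691 with scaling by totals alone. Among them were the VEGF receptor Kdr (3.47) and the adhesion molecule Vcam1 (5.32). Of 9 dendritic cell genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.18), and 2 of the 9 are on other lists. Too few genes were tested for camera in 4 lists, where 3 of 4 mast cell and basophil genes rose and 1 fell, 0 of 3 B cell genes rose and 1 fell, 0 of 4 erythroid and platelet genes rose and 1 fell, and 0 of 2 T and NK cell genes passed. Hdc, the histamine-forming enzyme of mast cells and activated macrophages, rose by 6.54 to 32.7 ± 3.11 CPM.

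KO-labelled macrophages responded to the control medium on a smaller scale. Gpr84, a receptor for medium-chain fatty acids, rose from 6.13 ± 0.884 to 41.0 ± 0.836 CPM (log2 2.73, SE 0.21, limma adjusted p = 5.87e-05), and Tnf rose from 48.7 ± 2.91 to 141 ± 11.7 CPM (log2 1.53). Plin2, the lipid droplet coat protein, fell from 1109 ± 85.0 to 248 ± 13.8 CPM (log2 −2.16, SE 0.08, limma adjusted p = 1.53e-06), and Cpt1a, which admits long-chain fatty acids to mitochondria, fell by 1.55. Of 24 sterol genes 14 rose, and Mrc1 and Arg1, markers of alternative activation, fell.

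In this comparison, which gives the response of KO cells to the medium, 1431 genes rose and 1192 fell. Scaling by totals alone gave 1170 up and 1387 down. The total of 2623 was 1359 without KO control 1, 1070 without KO control 2, 1586 without KO untreated 1 and 1243 without KO untreated 2, and 791 without both libraries of high factor. Besides Gpr84, the genes that rose most were the chemokine Cxcl10 (log2 2.4), the calcium pump Atp2b4 (1.98), Pald1 (1.97), the activation marker Cd69 (1.96) and Cmpk2 (1.89). Those that fell most were the mitochondrial mt-Co3 (−5.37, SE 1.67), whose KO control libraries stood far apart at 0.066 and 24.7 CPM and whose call was lost in 5 settings, Angptl4 (−3.92), the chemokine receptor Ccr1 (−2.75), the angiogenic factor Vegfa (−2.63), the guanine deaminase Gda (−2.41) and Nxpe5 (−2.33). Tlr4 was lower by 0.45 without passing (−0.45, SE 0.14, limma adjusted p = 0.0536). It passed in the same direction with the rlog table (adjusted p = 0.0494), the replicate block (0.00684), only these groups in the fit (0.0268) and scaling by totals alone (0.0221).

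Of 39 inflammatory genes, 22 rose, 2 fell and 15 did not pass in KO cells (25 and 2 adjusted over the list alone, camera adjusted p = 3.37e-09, adjusted p = 0.286 with an estimated correlation). Ccl4 rose by 1.57 and Ccl3 by 1.08, while Il1a (−0.99) and Tnfsf9 (−0.41) fell, calls that were lost in 9 and 7 settings. Of 49 interferon-stimulated genes, 23 rose, 1 fell and 25 did not pass (29 and 1 adjusted over the list alone, camera adjusted p = 6.54e-11, adjusted p = 0.478 with an estimated correlation), with Gbp2 up by 1.57 and the transcription factor Irf8 down (−0.40, a call lost in 5 settings). Of 34 immediate early genes, 15 rose, 3 fell and 16 did not pass (19 and 4 adjusted over the list alone, camera adjusted p = 0.000426, adjusted p = 0.324 with an estimated correlation), among them Btg2 (0.80) and Myc (1.21). Of 24 cholesterol genes, 14 rose, 1 fell and 9 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 4.06e-07, adjusted p = 0.324 with an estimated correlation), with Cyp51 at 1.12 and Idi1 at 0.93. Of 23 fatty acid oxidation genes, 0 rose, 12 fell and 11 did not pass (14 down adjusted over the list alone, camera adjusted p = 3.74e-07, adjusted p = 0.164 with an estimated correlation), including the carnitine carrier Slc25a20 (−0.89). In the lipid uptake and storage list 4 of 23 rose, 9 fell and 10 did not pass (4 and 9 adjusted over the list alone, camera adjusted p = 0.0977), with the lipid droplet protein Hilpda at −1.61. In the endoplasmic reticulum and integrated stress list 2 of 29 rose, 11 fell and 16 did not pass (2 and 13 adjusted over the list alone, camera adjusted p = 0.000114, adjusted p = 0.439 with an estimated correlation), with Ddit3 at −1.05 and Trib3 at −1.60. Of 22 alternative activation genes, 2 rose, 6 fell and 14 did not pass (5 and 6 adjusted over the list alone, camera adjusted p = 0.16), with Arg1 at −2.18, the mannose receptor Mrc1 at −1.45 and Clec10a at −1.57. Of 39 cell cycle genes, 0 rose, 2 fell and 37 did not pass (0 adjusted over the list alone, camera adjusted p = 0.0722). Of 28 glycolysis genes, 4 rose, 5 fell and 19 did not pass (4 and 8 adjusted over the list alone, camera adjusted p = 0.0425, adjusted p = 0.324 with an estimated correlation). Of 14 neutrophil genes, 0 rose, 3 fell and 11 did not pass (3 down adjusted over the list alone, camera adjusted p = 0.0644), and of 4 erythroid and platelet genes 2 fell and 2 did not pass.

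**Figure D2:**
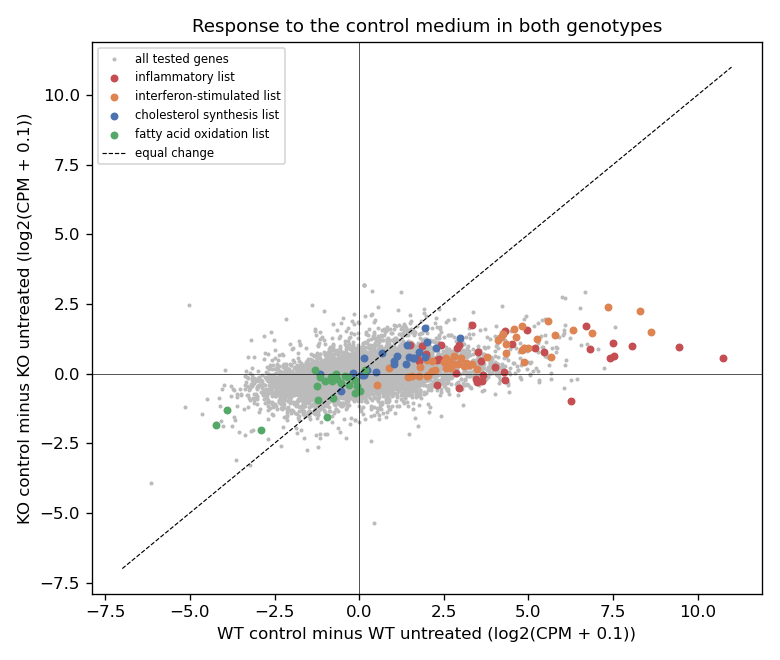
Log2 change after the control medium in KO-labelled cells (vertical axis) against that in WT-labelled cells (horizontal axis), each on the log2(CPM + 0.1) scale; each point is 1 of 13171 tested genes, 4 gene lists are coloured and the dashed line marks equal change. Across genes the slope is 0.169, and the inflammatory and interferon-stimulated genes lie to the right of and below the line.

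In the control medium the 2 genotypes were far apart. KO-labelled cells had lower levels of every tested inflammatory and interferon-stimulated gene than WT-labelled cells, and higher levels of most cell cycle genes. Il12b stood at 0.36 ± 0.0508 CPM in KO and 285 ± 73.2 CPM in WT cells (log2 −9.26, SE 0.23, limma adjusted p = 2.00e-09), and Il6 at 0.589 ± 0.0538 and 129 ± 7.53 CPM (log2 −7.55). Sesn1, a stress-inducible inhibitor of mTORC1 signalling, stood at 169 ± 8.78 CPM in KO and 13.7 ± 2.5 CPM in WT cells (log2 3.62). Wdfy1 and Lrmda differed in the same direction as in untreated cells, at 10.6 against 96.6 and 11.6 against 0.459 CPM.

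This comparison asks what the loss of TLR4 changes after the medium. In KO relative to WT cells 4113 genes were higher and 3940 lower. With scaling by totals alone the split was 7672 higher and 2076 lower, with the median of all genes at 0.503, and with the deposited scaling 2963 and 4934, with the median at −0.143. Besides Il12b and Il6, the lowest in KO cells were Ccl5 (log2 −8.72), Nos2 (−8.23), Cxcl9 (−7.82) and the granulocyte growth factor Csf3 (−7.42). The highest were Lrmda (4.38), Pald1 (4.31), St6gal1 (4.10), Gpr155 (4.07), Rnf150 (3.73) and Sesn1.

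All 39 inflammatory genes were lower in KO cells (39 adjusted over the list alone, median −3.67, camera adjusted p = 1.12e-21, adjusted p = 0.0577 with an estimated correlation), among them Ccl3 (−3.67) and the IL-1 receptor antagonist Il1rn (−4.24). All 49 interferon-stimulated genes were lower (49 adjusted over the list alone, median −3.30, camera adjusted p = 1.24e-24, adjusted p = 0.25 with an estimated correlation), with Gbp2 at −5.36 and Gbp5 at −6.10. Of 20 antigen presentation genes, 0 were higher, 17 lower and 3 did not pass (18 adjusted over the list alone, camera adjusted p = 6.43e-06, adjusted p = 0.384 with an estimated correlation), with Cd40 at −4.62. Of 26 inflammasome and cell death genes, 2 were higher, 18 lower and 6 did not pass (2 and 18 adjusted over the list alone, camera adjusted p = 1.12e-05, adjusted p = 0.121 with an estimated correlation), with Nlrp3 at −3.69 and the necroptosis effector Mlkl at −2.99. Of 34 immediate early genes 0 were higher, 28 lower and 6 did not pass (29 adjusted over the list alone, camera adjusted p = 4.02e-09, adjusted p = 0.121 with an estimated correlation), such as Fosl2 (−2.17) and the phosphatase Dusp1 (−2.42). In the Toll-like receptor pathway 7 of 39 were higher and 23 lower (8 and 25 adjusted over the list alone, camera adjusted p = 0.00234, adjusted p = 0.403 with an estimated correlation), which flipped to 14 and 12 with scaling by totals alone. Tlr3 was lower by 3.15 on the log2 scale (−3.15). Of 14 neutrophil genes 0 were higher, 12 lower and 2 did not pass (12 adjusted over the list alone, camera adjusted p = 6.99e-05, adjusted p = 0.384 with an estimated correlation).

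Of 28 glycolysis genes, 4 were higher, 23 lower and 1 did not pass (4 and 23 adjusted over the list alone, camera adjusted p = 1.06e-07, adjusted p = 0.0577 with an estimated correlation), with Slc2a1 at −2.45, the hexokinase Hk1 at −2.11 and, from the TCA cycle list, Acod1 at −4.49. Of 24 cholesterol genes, 2 were higher, 15 lower and 7 did not pass (2 and 16 adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.451 with an estimated correlation). In the lipid uptake and storage list 5 of 23 were higher, 16 lower and 2 did not pass (5 and 16 adjusted over the list alone, camera adjusted p = 0.00301, adjusted p = 0.121 with an estimated correlation). Of 23 fatty acid oxidation genes, 11 were higher, 4 lower and 8 did not pass (11 and 4 adjusted over the list alone, camera adjusted p = 0.0946), with Acadm at 1.47. In the eicosanoid list 8 of 15 were higher and 6 lower (8 and 6 adjusted over the list alone), with a median of 0.535, a mean of −0.241, Ptgs2 at −6.92 and a camera adjusted p of 0.591. Of 39 cell cycle genes, 32 were higher, 0 lower and 7 did not pass (32 adjusted over the list alone, camera adjusted p = 1.06e-06, adjusted p = 0.566 with an estimated correlation), with Bub1b at 2.71 and Kif20a at 2.47. Camera also placed 4 further lists lower in KO cells. For oxidative stress genes under NRF2 the counts were 4 higher and 14 lower of 22 (4 and 14 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.13 with an estimated correlation). For the stress list the counts were 5 and 17 of 29 (the same over the list alone, camera adjusted p = 0.0191, adjusted p = 0.566 with an estimated correlation). For phospholipid and sphingolipid genes the counts were 5 and 16 of 28 (the same over the list alone, camera adjusted p = 0.0329, adjusted p = 0.384 with an estimated correlation), which flipped to 12 and 10 with scaling by totals alone. For stromal genes the counts were 0 and 6 of 15 (the same over the list alone, camera adjusted p = 0.0385, adjusted p = 0.566 with an estimated correlation).

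The response to the control medium differed between genotypes for a large part of the transcriptome. The rise of Il12b, Ccl5 and Il1a in WT-labelled cells was not matched in KO-labelled cells, with differences between the responses (KO minus WT) of −10.2 (SE 0.33), −8.50 (SE 0.32) and −7.24 (SE 0.41) on the log2 scale (limma adjusted p = 4.60e-08, 9.03e-08 and 9.28e-07). In the other direction stood Pald1 (4.14), St6gal1 (3.93) and Gpr155 (3.88). Lpl, the lipoprotein lipase, rose in KO and fell in WT cells, from 2472 ± 290 to 4185 ± 317 CPM and from 2386 ± 40.3 to 1805 ± 99.4 CPM (difference 1.17, SE 0.14). Hilpda rose in WT and fell in KO cells (−3.25).

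The interaction tests this difference itself. It was called for 6039 genes, 2934 with a higher and 3105 with a lower change in KO cells. Scaling by totals alone gave 6518 and 1695, with the median of all genes at 0.516, and the deposited scaling 2057 and 3816, with the median at −0.121. All 39 inflammatory genes had a lower change in KO cells (39 adjusted over the list alone, camera adjusted p = 7.2e-25, adjusted p = 0.0567 with an estimated correlation), with Ccl3 at −3.43. So did all 49 interferon-stimulated genes (49 adjusted over the list alone, camera adjusted p = 9.53e-26, adjusted p = 0.235 with an estimated correlation), with Gbp2 at −4.76. Of 28 glycolysis genes 3 had a higher and 23 a lower change (3 and 23 adjusted over the list alone, camera adjusted p = 9.3e-08, adjusted p = 0.0567 with an estimated correlation), Ndrg1 being among the former (0.34, a call lost in 3 settings). Of 39 cell cycle genes 31 had a higher change and 0 a lower one (32 adjusted over the list alone, camera adjusted p = 4.61e-08, adjusted p = 0.451 with an estimated correlation). Of 24 cholesterol genes 1 had a higher and 11 a lower change (1 and 11 adjusted over the list alone, camera adjusted p = 0.00357, adjusted p = 0.451 with an estimated correlation), but with scaling by totals alone the counts were 4 and 7 and the median flipped from −0.453 to 0.0327. Camera also placed 8 further lists lower in KO cells. For immediate early genes the counts were 0 higher and 22 lower of 34 (0 and 23 adjusted over the list alone, camera adjusted p = 3.37e-07, adjusted p = 0.165 with an estimated correlation). For antigen presentation genes the counts were 0 and 16 of 20 (the same over the list alone, camera adjusted p = 3.56e-06, adjusted p = 0.331 with an estimated correlation). For inflammasome and cell death genes the counts were 2 and 16 of 26 (2 and 17 over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.163 with an estimated correlation). For neutrophil genes the counts were 0 and 10 of 14 (0 and 12 over the list alone, camera adjusted p = 0.000185, adjusted p = 0.331 with an estimated correlation). For the Toll-like receptor pathway the counts were 5 and 24 of 39 (the same over the list alone, camera adjusted p = 0.000444, adjusted p = 0.331 with an estimated correlation), which flipped to 11 and 9 with scaling by totals alone. For lipid uptake and storage genes the counts were 4 and 13 of 23 (the same over the list alone, camera adjusted p = 0.00312, adjusted p = 0.138 with an estimated correlation). For oxidative stress genes the counts were 3 and 13 of 22 (the same over the list alone, camera adjusted p = 0.0208, adjusted p = 0.165 with an estimated correlation). For phospholipid and sphingolipid genes the counts were 5 and 14 of 28 (the same over the list alone, camera adjusted p = 0.0392, adjusted p = 0.331 with an estimated correlation), which flipped to 11 and 8 with scaling by totals alone. The difference for Tlr4 was 0.42 (SE 0.20, limma adjusted p = 0.124). It passed with the replicate block (adjusted p = 0.0256) and with scaling by totals alone, where it was 0.90 (adjusted p = 0.00162).

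Where both genotypes responded, they mostly moved the same way. The calls shared 1061 genes that rose in both and 782 that fell in both, against 470 and 394 for independent lists, while 317 were called in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.452 and rho = 0.459. The median share of the WT log2 response seen in KO cells was 14% over the 39 inflammatory genes, 17.1% over the 49 interferon-stimulated genes, 42% over 18 called cholesterol genes, 35.7% over 19 called fatty acid oxidation genes, 12.3% over 35 called cell cycle genes and −4.29% over 27 called glycolysis genes. For the genotype difference, 8 genes were higher and 6 lower in KO cells in both media, against 3.44 and 3.29 for independent lists, and 2 were opposite (r = 0.263 and rho = 0.211 across genes). These comparisons share no library, but they use the same spread per gene.

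Poly(I:C) pre-treatment of KO-labelled cells went with high levels of the inflammatory and interferon genes that were low in KO cells after the control medium. Cxcl10 stood at 5422 ± 113 CPM, against 25.1 ± 3.91 in KO control cells, and Ccl5 at 2820 ± 68.9 against 3.12 ± 0.156 CPM (log2 9.77, SE 0.23, limma adjusted p = 7.25e-10). Nos2 reached 1834 ± 343 CPM (9.17) and Acod1 12368 ± 285 CPM (5.14). Cebpa, a transcription factor of myeloid differentiation, fell from 47.9 ± 3.67 to 3.09 ± 0.283 CPM (−3.91), and Scd2, a fatty acid desaturase, fell by 3.12.

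The comparison with KO control cells asks what Poly(I:C), which acts through TLR3 and cytosolic RNA sensors, does in cells labelled as lacking TLR4. The media may differ in more than Poly(I:C), since the labels do not give the rest of its composition. It called 4355 genes up and 4775 down. Scaling by totals alone gave 2081 and 8885, with the median of all genes at −0.755, and the deposited scaling 5203 and 3758, with the median at 0.129. The other genes that rose most were Cxcl9 (9.85), Cxcl11 (9.38), Il6 (8.96) and Il12b (8.88). Those that fell most were the glycosidase Engase (−5.23), Zfp395 (−5.18), Sesn1 (−4.94), the phosphatidate phosphatase Lpin1 (−4.72), the pro-apoptotic Bmf (−4.52) and Fam214a (−4.35).

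Of 39 inflammatory genes, 38 rose, 0 fell and 1 did not pass (38 adjusted over the list alone, camera adjusted p = 6.47e-19, adjusted p = 0.132 with an estimated correlation), with Ccl3 at 4.48, Ccl4 at 4.73 and Il1rn at 5.53. All 49 interferon-stimulated genes rose (49 adjusted over the list alone, camera adjusted p = 4.27e-23, adjusted p = 0.321 with an estimated correlation), with Gbp2 at 6.27 and Gbp5 at 7.17. In the Toll-like receptor pathway 25 of 39 rose and 8 fell (25 and 8 adjusted over the list alone, camera adjusted p = 0.00305, adjusted p = 0.378 with an estimated correlation), which flipped to 12 and 20 with scaling by totals alone, with Tlr3 at 4.07 and Myd88 at 2.26. Of 20 antigen presentation genes, 17 rose, 0 fell and 3 did not pass (17 adjusted over the list alone, camera adjusted p = 1.04e-05, adjusted p = 0.378 with an estimated correlation), with Cd40 at 5.68. Of 26 inflammasome and cell death genes, 20 rose, 3 fell and 3 did not pass (20 and 3 adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.172 with an estimated correlation), with Nlrp3 at 3.83 and Mlkl at 3.59. Of 34 immediate early genes, 30 rose, 1 fell and 3 did not pass (31 and 1 adjusted over the list alone, camera adjusted p = 1.58e-08, adjusted p = 0.172 with an estimated correlation). Of 14 neutrophil genes 12 rose, 0 fell and 2 did not pass (13 adjusted over the list alone, camera adjusted p = 0.000254, adjusted p = 0.378 with an estimated correlation), with Lcn2 at 3.79.

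Glycolysis genes rose in 22 of 28 cases and fell in 5 (22 and 5 adjusted over the list alone, camera adjusted p = 6.72e-05, adjusted p = 0.172 with an estimated correlation), with Hk1 at 1.98 and Slc2a1 at 2.32, though with scaling by totals alone the counts flipped to 11 and 13. Of 24 cholesterol genes 9 rose and 7 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.495), against 4 and 16 with scaling by totals alone. Of 18 fatty acid synthesis genes, 2 rose, 10 fell and 6 did not pass (2 and 10 adjusted over the list alone, camera adjusted p = 0.0559), with the desaturases Fads1 and Scd2 at −2.54 and −3.12. Of 23 fatty acid oxidation genes, 6 rose, 13 fell and 4 did not pass (6 and 13 adjusted over the list alone, camera adjusted p = 0.158), with Acadm at −1.90. In the stress list 14 of 29 rose and 9 fell (14 and 9 adjusted over the list alone, camera adjusted p = 0.217), which flipped to 6 and 15 with scaling by totals alone, with Nupr1 at 3.05 and Ppp1r15a at 3.33. Of 39 cell cycle genes, 4 rose, 29 fell and 6 did not pass (4 and 29 adjusted over the list alone, camera adjusted p = 7.64e-05, adjusted p = 0.599 with an estimated correlation). E2f2 was at −2.55 and the ribonucleotide reductase subunit Rrm2 at −2.87, while the replication clamp Pcna rose by 0.74, a call that was lost with scaling by totals alone (limma adjusted p = 0.972). Camera also placed 3 further lists higher. For lipid uptake and storage genes the counts were 15 up and 6 down of 23 (the same over the list alone, camera adjusted p = 0.0271, adjusted p = 0.191 with an estimated correlation), which flipped to 8 and 10 with scaling by totals alone. For TCA cycle and respiratory chain genes the counts were 19 and 3 of 36 (the same over the list alone, camera adjusted p = 0.0275, adjusted p = 0.423 with an estimated correlation), which flipped to 2 and 32 with scaling by totals alone. For alternative activation genes the counts were 13 and 4 of 22 (the same over the list alone, camera adjusted p = 0.0481, adjusted p = 0.599 with an estimated correlation).

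Against untreated KO cells, the genes that rose most with Poly(I:C) were Cxcl9 at 11.34, Ccl5 at 10.73 and Ifi205 at 10.51 (limma adjusted p = 2.19e-09, 2.59e-10 and 7.38e-10). Angptl4 fell by 7.30, Engase by 5.79 and Lpin1 by 5.51. This comparison asks for the whole response to the Poly(I:C) medium. It called 4605 genes up and 4855 down, and 2217 and 8703 with scaling by totals alone, where the median of all genes was −0.773. The deposited scaling gave 5436 up and 3997 down, with that median at 0.152. All 39 inflammatory and all 49 interferon-stimulated genes rose (39 and 49 adjusted over each list alone, camera adjusted p = 1.08e-18 and 4.25e-22, adjusted p = 0.135 and adjusted p = 0.341 with an estimated correlation). Of 23 fatty acid oxidation genes 2 rose, 18 fell and 3 did not pass (2 and 18 adjusted over the list alone, camera adjusted p = 0.00081, adjusted p = 0.179 with an estimated correlation). Of 24 cholesterol genes 14 rose and 5 fell (14 and 5 adjusted over the list alone, camera adjusted p = 0.0426, adjusted p = 0.596 with an estimated correlation), which flipped to 8 and 11 with scaling by totals alone. Of 39 cell cycle genes 1 rose, 29 fell and 9 did not pass (1 and 29 adjusted over the list alone, camera adjusted p = 4.6e-05, adjusted p = 0.596 with an estimated correlation). Camera also placed 6 further lists higher. For immediate early genes the counts were 31 up and 1 down of 34 (the same over the list alone, camera adjusted p = 1.1e-08, adjusted p = 0.179 with an estimated correlation). For antigen presentation genes the counts were 15 and 2 of 20 (the same over the list alone, camera adjusted p = 0.00081, adjusted p = 0.531 with an estimated correlation). For inflammasome and cell death genes the counts were 18 and 4 of 26 (the same over the list alone, camera adjusted p = 0.00081, adjusted p = 0.253 with an estimated correlation). For the Toll-like receptor pathway the counts were 29 and 6 of 39 (the same over the list alone, camera adjusted p = 0.000839, adjusted p = 0.482 with an estimated correlation), which flipped to 13 and 20 with scaling by totals alone. For glycolysis genes the counts were 22 and 5 of 28 (the same over the list alone, camera adjusted p = 0.00116, adjusted p = 0.179 with an estimated correlation), which flipped to 10 and 13 with scaling by totals alone. For neutrophil genes the counts were 10 and 1 of 14 (11 and 1 over the list alone, camera adjusted p = 0.00868, adjusted p = 0.548 with an estimated correlation). Tlr4 was at 0.32 (SE 0.14, limma adjusted p = 0.0703) and turned to −0.45 with scaling by totals alone (adjusted p = 0.00663). It passed as a rise with median-of-ratios scaling (0.36, adjusted p = 0.0481), the rlog table (0.36, adjusted p = 0.0441), the replicate block (0.32, adjusted p = 0.011), the deposited scaling (0.50, adjusted p = 0.0093) and without KO Poly(I:C) 1 (0.54, adjusted p = 0.00784).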

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

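The interaction of genotype and medium was planned, and the tests of explanations in this part were chosen only after the results were seen.

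What drew attention here was a difference between groups: the response to the control medium differed between genotypes by the interaction test for 6039 genes, 78 of which are named below. Values are KO minus WT responses on the log2(CPM + 0.1) scale. Among cytokines, chemokines and other inflammatory mediators the difference was −10.2 for Il12b, −8.5 for Ccl5, −7.24 for Il1a, −7.06 for Nos2, −6.91 for Ptgs2, −6.84 for Il6, −6.4 for Csf3, −5.89 for Edn1, −4.41 for Ptges, −3.79 for Il1rn, −3.64 for Lcn2, −3.43 for Ccl3, −3.38 for Ccl4, −2.76 for Tnf and −2.71 for Tnfsf9. Among interferon-inducible genes it was −7.13 for Cxcl9, −6.03 for Ifi205, −5.4 for Gbp5, −4.96 for Cxcl10, −4.76 for Gbp2, −3.88 for Phf11b, −3.69 for Cmpk2 and −0.94 for Irf8. Among receptors, adaptors and cell surface genes it was −4.3 for Cd40, −3.53 for Cd69, −3.36 for Gpr84, −3.04 for Tlr3, −2.19 for Cd14, −1.95 for Pdpn, −1.53 for Myd88, −1.21 for Ccr1 and −0.9 for Wdfy1. Among inflammasome, cell death and immediate early genes it was −3.72 for Nlrp3, −2.58 for Mlkl, −2.32 for Dusp1, −2.19 for Fosl2 and −0.73 for Btg2. Among markers of other cell types it was −5.63 for Vcam1, −5.52 for Hdc, −3.27 for Kdr, −2.94 for S100a8, −2.4 for S100a9, −1.52 for Csf3r and −0.44 for Mmp8. Among genes of glucose, purine and itaconate metabolism and of hypoxia and stress it was −4.2 for Acod1, −2.76 for Gda, −2.57 for Pfkfb3, −2.17 for Slc2a1, −1.84 for Hk1, −1.42 for Vegfa, −0.58 for Ddit3, 0.34 for Ndrg1 and −1.18 for Arg1. Among sterol and lipid genes it was −3.25 for Hilpda, −1.34 for Idi1, −1.22 for Plin2, −0.88 for Cyp51, −0.6 for Cpt1a, 1.17 for Lpl, 1.45 for Acadm, 2.24 for Angptl4 and 2.6 for Acot2. Among cell cycle genes it was 1.55 for Mcm4, 2.07 for E2f2, 2.13 for Aurkb, 2.65 for Kif20a and 2.76 for Bub1b. For the remaining named genes it was −3.94 for Akap2, 0.59 for Lrmda, 1.53 for Rab4a, 2.48 for Eps8, 2.95 for Kctd12b, 3.26 for Zdhhc14, 3.49 for Rnf150, 3.5 for Sesn1, 3.88 for Gpr155, 3.93 for St6gal1 and 4.14 for Pald1. The difference did not pass the test for Tlr4 (0.42), Zkscan3 (−0.09), Gng10 (−0.01), Ptprd (0.62), Atp2b4 (−0.30), mt-Co3 (−5.81), Nxpe5 (0.35), Slc25a20 (−0.12), Trib3 (0.21), Mrc1 (0.20), Clec10a (0.64) and Myc (0.03).

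The first pattern is the larger response of WT-labelled cells to the control medium, which covers all members of the inflammatory and interferon lists. Scaling does not account for it, since over 4 scalings the median interaction of the 88 list genes came no nearer to 0 than −2.46, while the median of all genes moved by at most 0.637 between scalings. Nor do pre-treated libraries under another genotype label than the untreated ones: 6 of 6 pre-treated libraries stood nearer to the untreated cells of their own label at most of 10 markers. Of these markers, Rpl35a-ps3 and Gm10243 may share reads and are not independent. Added granulocytes are argued against as the main source. The summed rise of 13 neutrophil-only genes was 1.55% of that of the inflammatory list (365 to 731 CPM against 2300 to 26000 CPM). Csf3r alone gave 444 of the 731 CPM. No granulocyte library gives the ratio to expect, so a smaller share of such cells is not excluded. Genotype labels exchanged in all groups at once cannot be told apart from correct ones, because the markers were picked by the untreated labels and Tlr4 (−0.53 in untreated cells, not called) was not lost under either label. A sample of another pre-treatment under the WT control label cannot be told apart from a response to the medium itself, because the WT change correlated at 0.94 across genes with the Poly(I:C) response of KO cells and both would raise these genes. A TLR4 ligand in the serum or albumin may also be the source, with a median of 14% of the WT inflammatory response left in KO cells, and this stays open because no library tests such a ligand, as does the genotype itself.

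The second pattern is the level of Tlr4 in KO-labelled libraries, −0.53 log2 from WT in untreated cells. Identical cells under both labels are argued against, because 7 of 10 markers found in untreated cells were called in the same direction between the control libraries. Of all 13171 tested genes, 61.1% were called there in either direction, 4113 higher and 3940 lower in KO cells. A call in a given direction is a stricter measure than this 61.1%. Among the markers 1 (Akap2) was called in the opposite direction, and the 2 not called, Rpl35a-ps3 and Gm10243, may share reads. The markers show that the cells differ, not that Tlr4 differs. Mice that differ elsewhere but share the same Tlr4 are therefore not excluded. A transcript that remains from the disrupted gene could give such a level (−0.53), but one value per gene does not show which exons were read, so that this stays open.

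The third pattern is the set of genes that differ between genotypes in untreated cells. Within 20 Mb of Tlr4, 3 of 98 tested genes were called (3.06%), against 19 of 13008 elsewhere (0.146%, Fisher's exact test, two-sided, p = 0.000563), which is consistent with a stretch of another strain carried along with the targeted gene. The test rests on these 3 genes, of which Gng10 lost its call in 5 settings, and Akap2 and Ptprd lost theirs with only the groups compared. There the log2 differences were 3.22 for Akap2, 3.86 for Ptprd and 0.75 for Gng10, no smaller than about the main values. Such a stretch does not contain the genes called on other chromosomes, and whether it could change them from a distance was not tested. The other chromosomes hold 11 of the 13 genes with a log2 difference over 2 in size. The 11 include the Rpl35a copies and Gm10243, which cannot be counted as separate differences. Gm10243 equalled Rpl35a-ps3 in every control and Poly(I:C) library. In untreated KO cells Gm10243 stood at 4.28 and 4.54 CPM and that copy at 0, as when shared reads are assigned differently. Whether the other calls come from other differences between the mice, from the loss of TLR4 or from shared reads among copies was not tested.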

How the results depend on the processing

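The added settings (deposited scaling, totals alone, both pseudocounts, voom on the recovered reads, and leaving out both libraries of high factor) were chosen only after the data were seen. The Wald test of DESeq2, listed beforehand in place of edgeR's test, was not run, because the deposited values are not raw counts.

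For KO against WT untreated cells the count of 22 became 14 with no filter on low values, 103 with the replicate block, 2 with only the groups compared and 13 without both libraries of high factor, and ranged from 12 to 55 with each library left out. For KO control against KO untreated cells the count of 2623 became 791 without both libraries of high factor and ranged from 1070 to 1586 with each library left out, where the lone library left is assumed to vary like the other groups. Fewer libraries in the fit leave fewer degrees of freedom, and the cause of the other moves was not tested. The other 5 comparisons stayed within 1.5 times of their counts under every setting run, from 6586 to 9748 for KO against WT control, 7580 to 9957 for the medium response of WT cells, 4927 to 8213 for the interaction, 7032 to 10966 for Poly(I:C) against control and 8367 to 10920 against untreated cells. Scaling by totals alone moves all genes of a comparison together, so that genes with small changes cross 0. Mostly for this reason 966, 1120, 484, 1643 and 1683 called genes of these 5 comparisons, in that order, changed sign under at least 1 setting, and 208, 294, 3, 976 and 960 were called the other way, all of them with scaling by totals alone. The shared genotype difference of 14 genes became 9 with no filter and 87 with the replicate block. Of the 78 set calls, 0 held with an estimated correlation. fry, which does not compare a list with other genes, gave a call in 121 of the 182 tests, 70 of them among the 78.

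Of 2727 alternative values of named genes, 2635 stayed on the same side of the threshold, 77 were no longer past it and 13 came past it. Another 2 reversed, that is, changed sign where the main or the alternative value was called. Changes of sign between values that were both not called are counted among the 2635. Both reversals were of Tlr4 with totals alone: 0.37 for KO against WT control and −0.45 for Poly(I:C) against untreated cells. Calls were lost in 4 or more settings by Il1a (9 settings), Tnfsf9 (7), Irf8 (5) and mt-Co3 (5) in the medium response of KO cells, by Cxcl3 (7) in the difference between the Poly(I:C) and medium responses, and by Cmpk2 (8), Phf11b (7), Rab4a (7), Gng10 (5), Pdpn (5) and Zkscan3 (4) between untreated cells. Voom on the recovered reads called 18, 8112, 8857, 2641, 6172, 8921 and 9361 genes for KO against WT untreated, KO against WT control, the medium response of WT and of KO cells, the interaction, and Poly(I:C) against control and untreated cells.

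Deviations of libraries with the same replicate number correlated at 0.0126 to 0.315 over 10 pairs of groups, above 0.1 in 6 of them. The main fit was planned without a replicate block, and the labels do not say that the numbers pair samples. All these correlations were positive, and the block raised the number of calls in every comparison, for example from 2623 to 3323 for the medium response of KO cells. A shared replicate effect is therefore not excluded. With the replicate block, Tlr4 in untreated KO against WT cells (−0.53) had an adjusted p of 0.0375, against 0.35 without it. Depth limits the lowest genes: 18.3 M recovered reads in KO control 2 is the smallest number. Its factor of 1.4545 makes 1 read stand for more units, on average, than in its replicate.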

Other observations

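The comparison of the Poly(I:C) and medium responses, its list counts and the test across genes were chosen only after the data were seen.

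The response of WT-labelled cells to the control medium and that of KO-labelled cells to Poly(I:C), each relative to untreated cells of the same label, covered largely the same genes although they share no library. The calls shared 3849 genes that rose in both and 3951 that fell in both, against 1512 and 1605 for independent lists, and 29 were called in opposite directions. Across genes the log2 changes correlated at r = 0.943 and rho = 0.927 with a slope of 1.15. Set against the change from KO control instead, 3441 rose and 3525 fell in both and 223 were opposite (r = 0.881).

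Many interferon genes had a larger response to Poly(I:C). Cxcl10, a chemokine induced by interferons, stood at 1377 ± 241 CPM in WT control and 5422 ± 113 CPM in KO Poly(I:C) cells, with a response larger by 2.80 log2 (SE 0.24, limma adjusted p = 0.000859). Ifnb1, which encodes interferon beta, was at 1.19 ± 0.376 CPM in WT control and 31.6 ± 2.28 CPM in Poly(I:C) cells, and was listed at 0 in untreated KO cells. The GTPase gene Gbp4 (2.66), Cmpk2 (2.46), Oasl1 (2.43) and the chemokine gene Ccl7 (2.35) also had larger responses to Poly(I:C). The change was lower with Poly(I:C) for Zfp395 (−2) and Cebpa (−1.59), which fell in both and fell further with Poly(I:C), and for the neutrophil chemokine gene Cxcl3 (−1.70), at 31.0 ± 0.717 CPM in WT control and 7.40 ± 1.58 CPM in Poly(I:C) cells. The call for Cxcl3 was lost in 7 settings. Of 49 interferon-stimulated genes 45 had a higher and 0 a lower signed change with Poly(I:C) (median 1.24), of 39 inflammatory genes 16 and 2, and of 24 cholesterol genes 0 and 8. With scaling by totals alone the inflammatory counts were 14 and 3 and the cholesterol counts 0 and 14. With the deposited scaling the cholesterol counts were 0 and 2. No test set these lists against other genes. Responses are relative to untreated cells of the same label, and the interferon-stimulated genes stood lower in untreated KO cells (median −0.548), which adds to their difference. Of all genes 1295 were called, 817 with a higher and 478 with a lower signed change, and a lower one includes genes that fell further. With scaling by totals alone the counts were 505 and 1962, while 41 of the 49 interferon-stimulated genes still had a higher change. The total fell to 438 without WT control 1, 582 without KO Poly(I:C) 2, 860 without KO Poly(I:C) 1, 695 without KO untreated 1, 689 without KO untreated 2 and 168 without both libraries of high factor. Genotype, stimulus and possibly time differ together here, so nothing in this difference (2467 genes with scaling by totals alone) separates them.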
